A study of Triticum aestivum with 18 samples.

How the data were processed

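RNA was measured in leaf tissue of 2 near-isogenic wheat lines, TXGBE273 (resistant to the greenbug aphid) and TXGBE281 (susceptible). Per the labels, plants were sampled at the 3-leaf stage at 0 h, and at 24 h and 48 h after infestation with greenbug biotype E, with 3 replicates in each of the 6 groups. The labels mark the 0 h samples as controls. Each of the 18 samples was hybridised to 1 Affymetrix wheat array as biotin-labelled RNA in 1 colour, per the labels' protocols.

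The deposited values were probe-set intensities from MAS5 on a linear scale, per the labels, which give no MAS5 version. In the deposited table the mean intensity of every array, with 2% of the probe sets trimmed at each end, was 500.1, so the authors had scaled the arrays to a common level. Detection calls are not given in the sources used here. Replicate origin is also not given there: the labels do not say whether replicates came from separate plants, so p-values measure the spread between these samples. With 3 arrays per group, the number of arrays limits the precision.

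The table held 61290 probe sets, of which 111 control probe sets were left out of the tests. Signals were analysed as log2(signal + 16), without further normalization between arrays. The offset of 16 understates the fold changes of dim probe sets. Probe sets above the array's own 40th percentile in at least 3 arrays were tested, which kept 46251 and removed 14928. One linear model with the 6 groups was fitted with limma 3.58.1 in R 4.3.3, with a moderated variance that followed the mean signal, and 11 comparisons were taken from it. Each comparison was adjusted by the Benjamini-Hochberg method, and "called" means an adjusted p under 0.05. On simulated data the model recovered 36% of 100 probe sets changed by 1 on the log2 scale between 0 h and 24 h in the resistant line. It recovered 65% of 100 probe sets changed by 2, with 9 false calls among 46251 probe sets. For the line by infestation comparison at 48 h the same steps recovered 17% and 48%, with 6 false calls. Nearly all probe sets were left unchanged in these simulations, whereas many more were called in the data. The adjustment depends on the share changed, so these recovered shares and false calls do not carry over to the data.

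Gene symbols came from the platform annotation, which is old and was used without gene titles. A single symbol was given for 1273 probe sets, several for 0 and none for 60017. Of the 771 annotated genes, 770 were found in the gene table of the IWGSC CS RefSeq v2.1 assembly, the exception being GAPN. The study names no assembly, so no coordinates are given. Only 102 genes had a name other than a LOC number, and 163 of their probe sets were tested. Wheat is hexaploid, so a probe set can also read the related copies of its gene on the other subgenomes. What each symbol stands for is general knowledge of wheat genes and was not stated in the annotation.

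The comparisons, the model, 31 gene lists and the rule for naming genes were chosen before the data were examined. By that rule, annotated genes were nameable in a comparison when called, with the 3 arrays of one group all on one side of the 3 arrays of the other, and among the 15 largest changes in either direction. No separation of arrays was asked for in the line by infestation comparisons. Chance alone separates the arrays in 1 of 10 splits of 6 arrays. Up to 4 members per direction of each gene list were also nameable, and at most 3 probe sets without a gene per direction. Genes named in one comparison were followed through the others. FBP, Pgk-1, XIP-I, WZF1, TSA, SAHH and UBC1 lie outside the rule and were named after their values were seen. Of the 31 lists, 17 had at least 1 tested probe set and 9 had at least 3, and these 9 were tested against all other probe sets with camera at a preset correlation of 0.01. A chloroplast group and a redox and detoxification group were assembled from gene symbols after the values were seen.

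The alternatives tried were quantile normalization, median centring, offsets of 1 and 64, no filter and stricter filters, limma without the variance trend or without moderation, array weights, fits to the compared arrays only, the replicate number as a block, and each array left out in turn. Scaling on the bacterial hybridisation controls was added after the data were seen. On that scale the median log2 change of all tested probe sets against 0 h was 0.60 and 0.39 in the resistant line and 0.33 and 0.57 in the susceptible line at 24 h and 48 h, against -0.018 and -0.0623, and -0.0666 and -0.0768, as deposited. All changes below are therefore relative to the common trimmed mean of the arrays. Line responses were compared by the difference of the changes from 0 h, called line by infestation below.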

Results

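The series profiled leaves of a greenbug-resistant wheat line, TXGBE273, and its susceptible near-isogenic partner, TXGBE281, through the first 48 h of aphid infestation. Each line had 3 arrays at 0 h, 3 at 24 h and 3 at 48 h. No uninfested plants at 24 h or 48 h were analysed here, so each difference from 0 h covers infestation together with plant age and time of sampling. The first principal component held 42.4% of the variance and set the 0 h groups (means -128.3 resistant and -129.8 susceptible) apart from the infested groups (37.1 to 102.9). The second component, with 9.0%, parted the lines after infestation, with means of -55.7 and -56.5 in the resistant and 30.1 and 58.1 in the susceptible line.

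**Figure D1:**
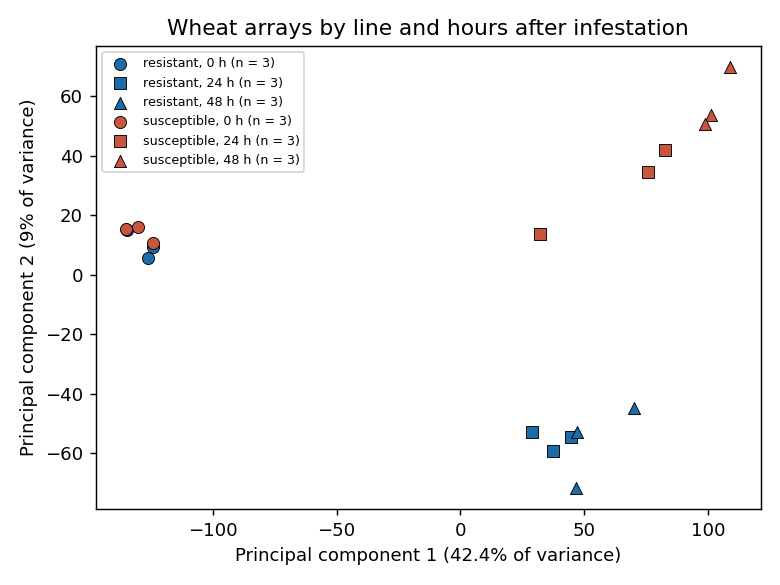
Each point is 1 array placed by its first and second principal component scores over the tested probe sets, with the share of variance on each axis. The 0 h arrays of both lines sit together at means of -128.3 and -129.8 on the first axis, and the infested arrays of the lines part on the second.

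The comparison of infested with 0 h leaves asked which genes respond to greenbug feeding in each line. PR5, a thaumatin-like pathogenesis-related gene, rose strongly in both lines at both times. The xylanase inhibitor gene XIP-I, the zinc-finger gene WZF1 and the lignin-pathway gene COMT1 rose in both lines too. TaPrx1, the glyoxalase gene lgul, the ribosomal protein gene RPL9, the methyltransferase gene PEAMT1 and the glyceraldehyde phosphate dehydrogenase gene GAPN fell steeply. PsbP, PRK, FBP and the rbcL probe set with the largest fall, all of photosynthesis or carbon fixation, were lower in both lines. The catalase gene CAT1 was lower too. The light harvesting and carbon fixation lists had only part of their probe sets lower. Both lists, and the redox list that holds CAT1, lost their calls with an estimated correlation.

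In the resistant line the PR5 signal went from 1410 ± 799.6 (SD, n = 3) at 0 h to 13080 ± 7644 at 24 h and 9141 ± 3040 at 48 h. The PR5 log2 changes were 3.24 ± 0.42 (SE, limma adjusted p = 4.25e-06) and 2.82 ± 0.42 (adjusted p = 1.98e-05). In the susceptible line PR5 rose by 3.66 (adjusted p = 7.34e-07) and 3.73 (adjusted p = 3.95e-07) on the log2 scale. XIP-I rose by 1.33 and 1.70 in the resistant and by 1.63 and 1.88 in the susceptible line. WZF1 rose by 1.51 and 1.77 in the resistant and by 1.01 and 1.82 in the susceptible line. COMT1 changes lay between 0.63 and 0.70 in all 4 comparisons. For each of these genes the 3 infested arrays lay above the 3 arrays at 0 h in every comparison. The call and direction of PR5, XIP-I, WZF1 and COMT1 held in every alternative, each array left out in turn included.

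TaPrx1 had a signal of 18980 ± 3320 (SD, n = 3) at 0 h and 1521 ± 631.2 at 24 h in the resistant line, and 17590 ± 1822 and 940.4 ± 583.5 in the susceptible line. Its log2 changes were -3.72 and -3.97 in the resistant and -4.36 and -4.04 in the susceptible line, with adjusted p between 1.41e-09 and 1.76e-08. One lgul probe set changed by -2.86 and -3.41 in the resistant and -3.10 and -3.80 in the susceptible line. RPL9 changes ran from -2.99 to -3.63 over the 4 comparisons. GAPN fell by 2.70 and 2.81 in the resistant and by 3.19 and 4.02 in the susceptible line. PEAMT1 fell by 3.17 and 2.34 in the resistant and by 3.69 and 3.61 in the susceptible line. In every one of these comparisons all 3 infested arrays lay below all 3 arrays at 0 h. RPS29, the other ribosomal protein gene of its list, had 1 probe set higher and 1 lower at 48 h in both lines.

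PsbP, of photosystem II, had a signal of 53930 ± 2474 (SD, n = 3) at 0 h in the resistant line, and 16150 ± 2155 at 48 h. PsbP changed by -1.39 and -1.75 in the resistant and by -1.82 and -2.55 in the susceptible line. One probe set of the Rubisco large-subunit gene rbcL changed by -2.69 and -2.73 in the resistant and -3.88 and -3.30 in the susceptible line. PRK changes lay between -1.73 and -2.34, and FBP changes between -2.34 and -3.21. CAT1 fell by 1.86 and 1.84 in the resistant and by 1.91 and 2.43 in the susceptible line. The thioredoxin gene Trx-M fell by 1.85 at both times in the resistant line, and by 1.79 and 2.37 in the susceptible line. PsbO fell by 0.68 and 0.73 in the resistant and by 0.64 and 0.95 in the susceptible line as deposited. Under quantile normalization its change at 24 h in the resistant line flipped to 0.04, and no PsbO change from 0 h was called, as was also the case on the hybridisation control scale, which gave the same 0.04.

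The carbon fixation list (21 probe sets of PRK and rbcL) had 8 and 10 probe sets lower in the resistant line at 24 h and 48 h, and 12 and 11 lower in the susceptible line, with 0 higher. Adjusted over the list alone, 8, 11, 12 and 11 were lower. Against all other probe sets the list was lower with camera adjusted p of 0.00684, 0.00472, 0.00404 and 0.00684, and adjusted p = 0.137 with an estimated correlation in each. Quantile normalization lifted the first to 0.0541. Light harvesting and photosystem genes (5 probe sets of PsbO, PsbP and petC) had 4 lower in each comparison, and 1 dim petC probe set was higher in the resistant line. Adjusted over the list alone, the same 4 and 1 were found, and the dim one was also higher in the susceptible line at 24 h. Camera adjusted p was 0.0170, 0.0134, 0.0125 and 0.00684, and adjusted p = 0.328, 0.317, 0.317 and 0.283 with an estimated correlation. Quantile normalization lifted the first 3 camera values without an estimated correlation to 0.576, 0.437 and 0.168, the hybridisation control scale lifted the first to 0.193, and the brightest signals had fallen from means of 91890 and 79100 at 0 h to between 49300 and 59150. Redox enzymes (CAT1 and Trx-M, 3 probe sets) had 3, 3, 2 and 3 lower, also adjusted over the list alone, with camera adjusted p from 0.00472 to 0.0134 and adjusted p = 0.137 to 0.161 with an estimated correlation. Of the 5 probe sets on the list of class III peroxidases, which came from TaPrx1 and PER1, 4 were lower in each comparison. Both symbols are also in use for peroxiredoxins, so the name of that list need not describe them. Adjusted over the list alone, 4 were lower in each and 1 was higher in the resistant line at both times. Its camera adjusted p was 0.00684, 0.00915, 0.00684 and 0.00684, and adjusted p = 0.245 or 0.246 with an estimated correlation.

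No other list tested by camera was called in these 4 comparisons. Glc1, a glucanase gene, was the single gene of the chitinase and glucanase list, with 1 of 2 probe sets higher in all comparisons but the resistant line at 24 h, also adjusted over the list alone. The fructan hydrolase gene 1-FEH was higher and the starch-synthesis gene AGP-S lower in all 4 comparisons as deposited, while AGP-S turned to 0.38, called as higher (adjusted p = 0.0447), and to 0.08, without a call, in the resistant line on the hybridisation control scale. The call of 1-FEH in the resistant line at 24 h, 0.38, was lost without resistant 0 h replicate 2 (0.31). That of AGP-S, -0.34, was lost without resistant 0 h replicate 2 (-0.27) or 24 h replicate 2 (-0.29). GSTZ1, the one gene of the glutathione S-transferase list, had 3, 2, 3 and 1 of 3 probe sets lower, with camera adjusted p of 0.0842 or above. On the hybridisation control scale GSTZ1 turned to 0.35 and 0.20 in the resistant line and to 0.19 in the susceptible line at 24 h. The histone and cell division list (18 probe sets) went both ways, with 4 higher and 4 lower, then 3 and 2, in the resistant line and 6 and 2, then 7 and 2, in the susceptible line. Adjusted over the list alone only the last changed, to 8 higher, and camera adjusted p was 0.318 or above. In that list tubb2 was higher at 1.84 and 1.29 in the resistant line and Tubb4 lower at -0.61 and -0.62, the 24 h value of Tubb4 turning to 0.10 on the hybridisation control scale. The cold, drought and abscisic acid list had 2 of 3 probe sets lower at 24 h and 1 at 48 h in the resistant line, and 0 in the susceptible line, also adjusted over the list alone, with camera adjusted p of 0.409 or above. The serpin gene WSZ2a on the protease inhibitor list rose by 2.22 in the susceptible line at 48 h and had a value of 0.11 in the resistant line. The cuticle marker LTP3 was called in the susceptible line at 48 h (0.34), a call lost without 0 h replicate 1 (0.31), 48 h replicate 1 (0.24) or 48 h replicate 2 (0.33). The reference gene TEF1 had values of 0.23 in the resistant and 0.27 in the susceptible line at 24 h. No call was made by limma for the cell wall gene XTH or for the 6 grain marker probe sets, whose camera adjusted p was 0.77 or above in these 4 comparisons. The heat shock list had no tested probe set. No annotated gene matched the lists of lectins, jasmonate, salicylate and ethylene, benzoxazinoids, WRKY and other transcription factors, resistance proteins, calcium signalling, nitrogen and senescence, auxin, vascular, anther and root genes.

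In number, limma called 14872 probe sets at 24 h and 15595 at 48 h in the resistant line, and 15458 and 17064 in the susceptible line. In the resistant line 8144 were higher and 6728 lower at 24 h, and 8040 and 7555 at 48 h. In the susceptible line 7926 were higher and 7532 lower at 24 h, and 8250 and 8814 at 48 h. Of the 1096 annotated probe sets, 547 and 571 were called in the resistant and 558 and 598 in the susceptible line. The balance of directions depended on the scale: on that of the hybridisation controls, 17742 were higher and 2236 lower in the resistant line at 24 h. The 4 genes LOC543330 (4.89 and 5.16 at 24 h in the resistant and susceptible line), LOC543287 (4.38 and 5.38), LOC543104 (-4.95 and -5.20) and LOC100037528 (-4.68 and -5.03) had the largest changes at 24 h that both lines shared among genes without a name, ranked by the line with the smaller change. Among probe sets without a gene, the largest changes in the susceptible line at 48 h were 9.46 and -7.26.

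**Figure D2:**
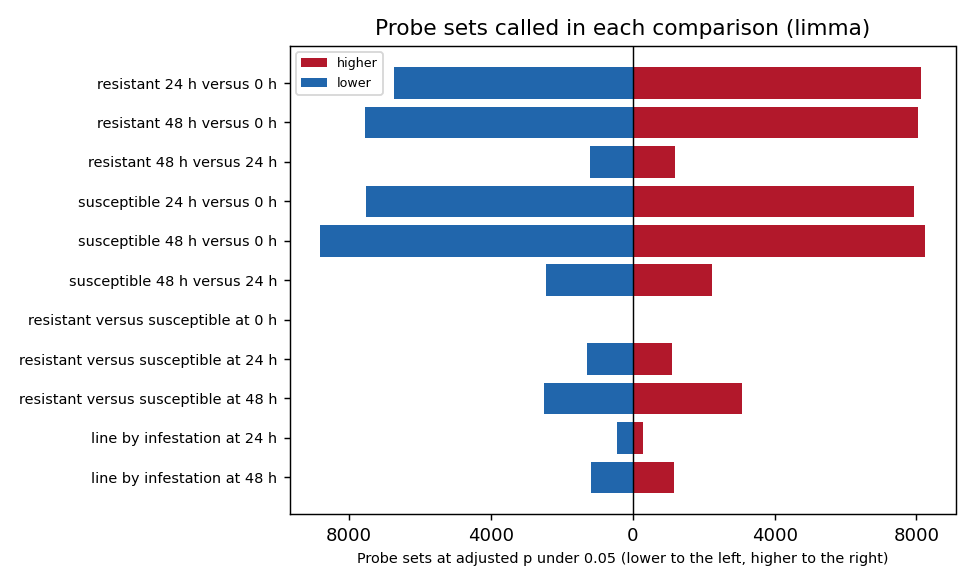
Bars give the number of probe sets called by limma in each of the 11 comparisons, lower to the left and higher to the right. The bars against 0 h hold 14872 to 17064 probe sets, while that between the lines at 0 h holds 10.

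The lines shared most of their responses. At 24 h, 11006 probe sets were called in the same direction in both lines and 84 in opposite directions, against 2491 in the same direction from independent lists. At 48 h the numbers were 11513, 160 and 2874. The lines have separate 0 h arrays. Within a line, 11606 (resistant) and 12333 (susceptible) probe sets were called alike at 24 h and 48 h, with 31 and 57 opposite, where independent lists would share 2515 and 2849. Those comparisons share their 0 h arrays, which cannot be split with 3 per line, so part of the excess may come from the shared controls. Across probe sets, which are not independent replicates, the covariance of the 24 h and 48 h changes was 0.740 and 0.974, against 0.0816 and 0.0817 in 20 simulations without effects. The correlations were 0.864 and 0.876, against 0.498 and 0.499.

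Between 24 h and 48 h of infestation the question was which genes kept moving. In both lines LOC543233, LOC543363 and LMGli2482, whose symbol is of the gliadin type, rose, and lgul, LOC100125679, the gibberellin oxidase gene GA20ox1D and the immunophilin gene FKBP70 fell. LOC543234 was called, as higher, in the resistant line only. Glc1, WZF1 and the chromatin gene Hmgb3 (higher) and PsbP (lower) were called in the susceptible line only. A call in a single line is not a difference between the lines, which was not tested for this interval.

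FKBP70 changed by -1.01 ± 0.11 (SE, adjusted p = 2.73e-05) from 24 h to 48 h in the resistant line, all 3 arrays at 48 h lying below the 3 at 24 h. In the susceptible line FKBP70 changed by -0.57 (adjusted p = 0.00159), and -0.30 without a call on the hybridisation control scale. LOC543233 rose by 4.06 in the resistant and 1.84 in the susceptible line, and LOC543363 by 1.63 and 1.23, whereas LOC100125679 fell by 1.63 and 2.66. LOC543234 rose by 3.55 in the resistant line. GA20ox1D changed by -2.13 in the resistant line (adjusted p = 0.0154), a call lost without resistant 24 h replicate 2 (-1.93), 24 h replicate 3 (-1.95) or 48 h replicate 1 (-2.01). In the susceptible line GA20ox1D changed by -1.77 (adjusted p = 0.026), a call lost in 4 of the 6 fits that each left out 1 of the arrays compared, and at -1.34 without susceptible 48 h replicate 3. In that line Glc1 rose by 0.97 (adjusted p = 0.00152), WZF1 by 0.81 and Hmgb3 by 0.60 between these times. Another lgul probe set fell by 1.93 in the susceptible line (adjusted p = 0.00136) and by 1.60 in the resistant line (adjusted p = 0.0119), the latter call lost without resistant 24 h replicate 2 (-1.49) or 48 h replicate 1 (-1.11). PsbP fell by 0.73 in the susceptible line on the deposited scale, and on the hybridisation control scale by 0.45 without a call. One LMGli2482 probe set had a signal of 92.9 ± 91.9 (SD, n = 3) at 24 h and 1925 ± 860.7 at 48 h in the susceptible line, a change of 4.60 ± 0.70 (SE, adjusted p = 0.000242). In the resistant line this LMGli2482 probe set changed by 2.54 ± 0.70 (adjusted p = 0.0398), a call lost in 5 of the 6 fits that each left out 1 of the arrays compared. Light harvesting genes had 3 of 5 probe sets lower in the susceptible line, 4 adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.317 with an estimated correlation). Redox enzymes had 2 of 3 lower, 3 adjusted over the list alone (camera adjusted p = 0.0205, and adjusted p = 0.179 with an estimated correlation). From 24 h to 48 h, limma called 2390 probe sets in the resistant line (1186 higher, 1204 lower) and 4687 in the susceptible line (2228 higher, 2459 lower). Without the variance trend the resistant count was lower than in any fit with 1 array left out. In such fits it was 1265 without 24 h replicate 1, 1524 without 24 h replicate 2 and 1502 without 48 h replicate 2. On the hybridisation control scale 303 were higher and 1102 lower in the resistant line. The susceptible count was 2924 without 24 h replicate 2 and 2904 without 48 h replicate 3, and on that scale 3199 were higher and 496 lower.

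Before infestation few probe sets were called between the lines. No annotated gene was called between them at 0 h, TaGlu1a (0.82) and LOC543233 (1.35) included. With 3 arrays per group a difference may have missed its call. Mean signals of LOC543234 (823.4 and 348.9) and LOC543363 (2406 and 1383) were also higher in the resistant than the susceptible line. That of LOC543438 was too (281.1 and 131.8), although it was lower there after infestation, and that of LOC543085 was not (268.7 and 295). Of 46251 probe sets tested, 3183 had an unadjusted limma p under 0.05, above the share of 0.05 expected without any difference. The 10 probe sets called by limma, 5 higher and 5 lower in the resistant line, carried no gene. The one with the largest difference had a signal of 100.2 ± 74.2 (SD, n = 3) in the resistant and 786.4 ± 105.6 in the susceptible line, a log2 difference of -2.96 (adjusted p = 0.00633) with the 3 arrays of each line apart. It differed by -2.43 at 24 h and -2.89 at 48 h, one of 3 probe sets called in the same direction at all times. The next largest differences at 0 h were -2.61 and 2.19. The count was 6 without resistant 0 h replicate 3 and 18 without susceptible 0 h replicate 1.

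After infestation the comparison of the lines asked which genes set resistant plants apart under attack. TaGlu1a, a beta-glucosidase gene, was far higher in the resistant line at 24 h and 48 h. LOC543233, LOC543234 and LOC543363 were likewise higher, and LOC543085 and LOC543438 lower, in the resistant line at both times. At 48 h the resistant line had more PsbP, PEAMT1 and GAPN signal. It had less Glc1, LMGli2482 and signal of the abscisic acid responsive gene Rab15.

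TaGlu1a signal was 1797 at 0 h, 3147 at 24 h and 1741 at 48 h in the resistant line, and 985, 131 and 80.1 in the susceptible line. The lines differed by 4.43 ± 0.28 (SE, adjusted p = 5.44e-09) at 24 h and 4.08 ± 0.28 (adjusted p = 6.21e-09) at 48 h, the 3 arrays of each line apart. LOC543233 differed by 5.14 and 7.36, with 34150 ± 8490 (SD, n = 3) in the resistant and 189.5 ± 34.8 in the susceptible line at 48 h. LOC543363 differed by 5.54 and 5.94, LOC543234 by 3.90 and 6.28, and LOC543085 by -4.36 and -4.02. At 48 h PsbP differed by 0.92 (adjusted p = 0.000351), PEAMT1 by 1.22 (adjusted p = 0.00073) and GAPN by 1.17 (adjusted p = 0.00617). PRK (0.82) and CAT1 (0.69) were also called at 48 h, but not on the hybridisation control scale (0.52 and 0.38). Glc1 differed by -0.92 (adjusted p = 0.00185), Rab15 by -2.56 (adjusted p = 0.0002) and LMGli2482 by -3.84 (adjusted p = 0.00132). 1-FEH was lower in the resistant line by -0.52 at 24 h and -0.50 at 48 h, the former without a call on the hybridisation control scale (-0.37). Hmgb3 was higher in the resistant line at 24 h by 0.56 (adjusted p = 0.00163).

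As a group, light harvesting genes were higher in the resistant line at 48 h, with 4 of 5 probe sets called, also adjusted over the list alone (camera adjusted p = 0.00472, and adjusted p = 0.245 with an estimated correlation). At 24 h 1 was called, 2 adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.405 with an estimated correlation), and median centring and quantile normalization lifted the first to 0.0611 and 0.0831. Carbon fixation had 1 probe set higher in the resistant line at 24 h, 3 adjusted over the list alone (camera adjusted p = 0.00684, and adjusted p = 0.137 with an estimated correlation). The cold, drought and abscisic acid list, 3 probe sets, had 2 lower at 48 h, also adjusted over the list alone (camera adjusted p = 0.0254, and adjusted p = 0.245 with an estimated correlation). At 24 h it had 0, 2 adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.245 with an estimated correlation). Histone and cell division genes had 2 lower at 48 h, 3 adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.140 with an estimated correlation). The ribosomal protein list had 1 higher at 24 h, 2 adjusted over the list alone (camera adjusted p = 0.0337, and adjusted p = 0.177 with an estimated correlation). Between the lines limma called 2382 probe sets at 24 h (1099 higher and 1283 lower in the resistant line) and 5586 at 48 h (3094 and 2492). Of these, 1830 were called in the same direction at both times and 1 in opposite directions, against 142.6 from independent lists. The 24 h count was 1577 without resistant 24 h replicate 3, 1431 without susceptible 24 h replicate 3 and 3231 without susceptible 24 h replicate 2. The majority direction at 24 h turned from lower to higher on the hybridisation control scale. The 48 h count was 3614 without resistant 48 h replicate 2 and 3370 without susceptible 48 h replicate 3, and on the hybridisation control scale 904 were higher and 3979 lower.

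**Figure D3:**
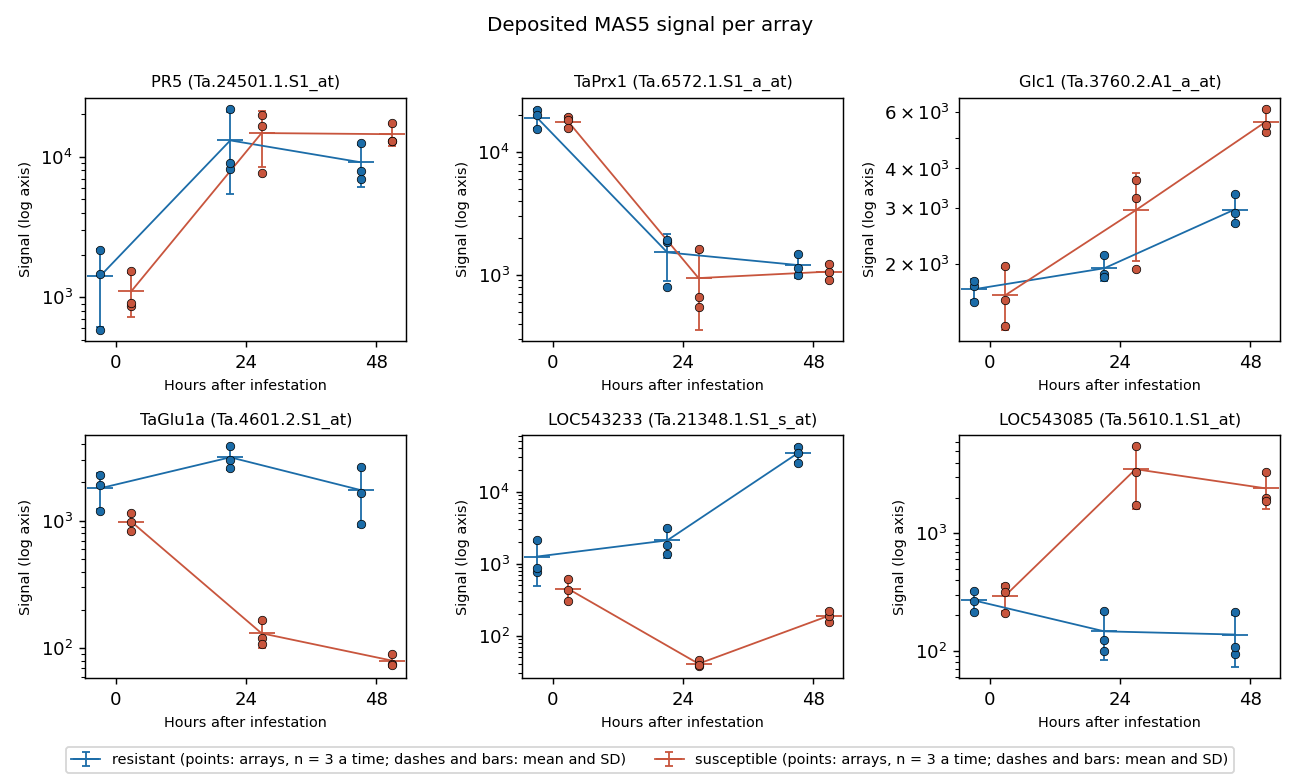
Signal of 6 probe sets per array on a log axis, against hours after infestation, for each line, with dashes and bars giving the mean and SD of 3 arrays. PR5 rises and TaPrx1 falls in both lines, while TaGlu1a stays between means of 1741 and 3147 in the resistant line and falls to 80.1 in the susceptible line.

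Whether the lines responded differently was tested as the line by infestation difference. Without uninfested plants at 24 h or 48 h, that difference also covers any line difference with plant age or time of sampling. The response of TaGlu1a, which fell in the susceptible line, differed between the lines at both times. LOC543233 and LOC543363 rose in the resistant and fell in the susceptible line at 48 h. LOC543085 rose in the susceptible line, and LOC543438, LOC543196 and LOC543399 rose far more there.

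TaGlu1a fell by 2.77 and 3.37 in the susceptible line at 24 h and 48 h. In the resistant line its change was 0.83 at 24 h, a call lost without resistant 0 h replicate 1 (0.57), 24 h replicate 1 (0.68) or 24 h replicate 3 (0.86), and -0.12 at 48 h. On the hybridisation control scale the last of these flipped to 0.42. The response of TaGlu1a differed between the lines by 3.61 ± 0.40 (SE, adjusted p = 3.19e-05) at 24 h and 3.26 ± 0.40 (adjusted p = 3.74e-05) at 48 h, with 3 arrays per group. LOC543233 changed by 4.87 in the resistant and -1.14 in the susceptible line at 48 h, a difference of 6.01 (adjusted p = 1.28e-07). The susceptible value was -0.90 and not called without susceptible 0 h replicate 1, nor was it on the hybridisation control scale. LOC543363 changed by 2.84 and -2.38, a difference of 5.22 (adjusted p = 1.01e-07). LOC543085 changed by 2.95 in the susceptible line and had a value of -0.95 in the resistant line, a difference of -3.90 (adjusted p = 8.37e-05). LOC543438 rose by 2.86 in the resistant and 6.23 in the susceptible line, a difference of -3.37 (adjusted p = 4.14e-05). The differences of LOC543196 and LOC543399 at 48 h were -3.50 and -3.96, and LOC606359 differed by 4.02 at 24 h. The calls of all differences in this paragraph held with each array left out in turn.

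Line by infestation calls of Glc1 (-0.997), PEAMT1 (1.26), PsbP (0.81), Rab15 (-2.19) and LMGli2482 (-3.84) at 48 h were lost in 7, 6, 10, 8 and 10 of the 12 fits that each left out 1 array. Light harvesting genes had 1 of 5 probe sets with a difference at 48 h, 2 adjusted over the list alone (camera adjusted p = 0.0355, and adjusted p = 0.416 with an estimated correlation), and the hybridisation control scale lifted the first to 0.19. The cold, drought and abscisic acid list had 1 of 3, 2 adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.246 with an estimated correlation). Histone and cell division genes had 2 of 18, also adjusted over the list alone (camera adjusted p = 0.0355, and adjusted p = 0.161 with an estimated correlation), and quantile normalization lifted the first to 0.0645. In total limma called 738 probe sets at 24 h (290 with a more positive and 448 with a more negative change in the resistant line) and 2337 at 48 h (1168 and 1169). The balance of directions depended on the scale at both times. Both counts were lower without the variance trend than with any array left out. The 24 h count was 1304 without susceptible 24 h replicate 2 and 476 without susceptible 24 h replicate 3. The 48 h count was 1507 without resistant 48 h replicate 2 and 1266 without susceptible 48 h replicate 3.

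**Figure D4:**
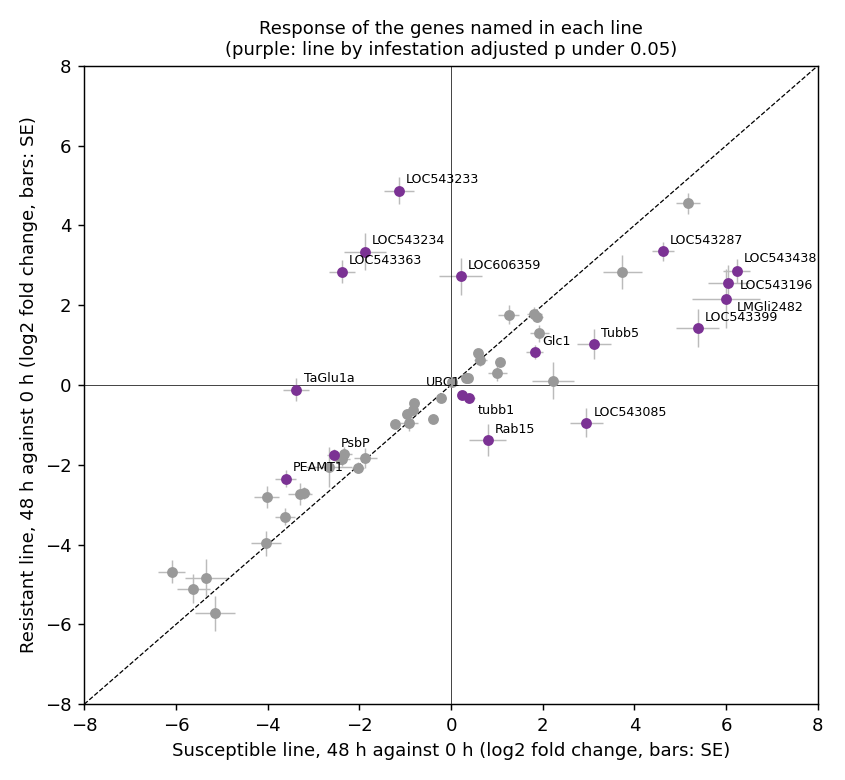
Log2 fold change at 48 h against 0 h in the susceptible (horizontal) and resistant line (vertical), for a single probe set per named gene. Points carry SE bars and are purple where the line by infestation adjusted p was under 0.05. Most lie near the dashed line of equal response, while TaGlu1a sits at -3.37 and -0.12 and LOC543233 at -1.14 and 4.87.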

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

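The tests of array scaling, RNA degradation, wrong line labels and a sequence difference were chosen only after the result was seen, as were the wheat control probe sets and the scaling on hybridisation controls.

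The lines differed in their change from 0 h for 738 probe sets at 24 h and 2337 at 48 h, which brought them here because the difference itself was tested. Among named genes, TaGlu1a differed by 3.61 at 24 h and 3.26 at 48 h. Glc1 (-0.997), LMGli2482 (-3.84), Rab15 (-2.19), tubb1 (-0.72) and Tubb5 (-2.09) had the more positive change in the susceptible line at 48 h. UBC1 did so on both of its called probe sets (-0.50 and -1.10). PEAMT1 (1.26) and PsbP (0.81) had the less negative change in the resistant line at 48 h, and Hmgb3 (0.60) the more positive one at 24 h. TaGlu1a kept its call in all 25 alternatives at both times. Over the same 25, the call changed in 9 for Glc1, 14 for LMGli2482, 9 for Rab15, 10 for tubb1, 9 for Tubb5, 4 and 0 for the UBC1 probe sets, 9 for PEAMT1, 14 for PsbP and 16 for Hmgb3.

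Control probe sets left out of the comparisons also moved with infestation. The 3 prime, middle and 5 prime probe sets of the wheat glucose-6-phosphate dehydrogenase control G-6-PDH changed by 0.56, 0.48 and 0.46 in the resistant line at 48 h, the last without a call, and by 2.22, 1.82 and 2.06 in the susceptible line, with line by infestation differences of -1.67, -1.34 and -1.60. Those of the sucrose synthase control changed by 0.25, 0.35 and -0.13 in the resistant line, the last without a call, and by 0.65, 1.03 and 0.71 in the susceptible line. The differences were -0.41, -0.67 and -0.85, the last without a call. The bacterial hybridisation controls, which are added to each sample, lay at -0.72 and -0.54 against 0 h in the resistant line and at -0.47 and -0.74 in the susceptible line, at 24 h and 48 h.

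The first pattern weighed is the large number of probe sets, from 14872 to 17064, that differed between 0 h and infested leaves in both lines. For array scaling, the measure was the share of calls, higher and lower pooled, that kept call and direction. That share was at least 69.2% over quantile normalization, median centring and hybridisation control scaling, only just above the bound set for it. Hybridisation control scaling raised the infested arrays as a whole, so higher calls could hardly be lost there and the pooled share cannot decide. Under quantile normalization and median centring at least 90.7% of calls kept call and direction, so most did not depend on those choices. The balance of higher and lower calls did depend on the scale. On the hybridisation control scale, lower calls dropped from 6728 and 7555 to 2236 and 3167 in the resistant line at 24 h and 48 h. In the susceptible line they dropped from 7532 and 8814 to 3631 and 3559. Most lower calls were therefore not kept on that scale, and array scaling stays open as their cause. RNA degradation stays open. The 3 prime over 5 prime signal ratios of the 3 bright wheat controls (ubiquitin, G-6-PDH and sucrose synthase) differed by at most 0.38 on the log2 scale, against a median change of at least 0.992 among called probe sets. Those of the 4 dim controls, with mean signals under 300, differed by up to 2.07 and in both directions, from -2.07 for actin to 1.34 for ef1a, with wide 95% limits, and the 18S ribosomal RNA control changed by -0.94 and -1.40 in the resistant and -1.55 and -1.96 in the susceptible line, the first without a call. Plant age or time of sampling cannot be told apart from infestation, because 0 uninfested arrays at 24 h or 48 h were analysed. A response to feeding, with PR5 up and PsbP, rbcL and TaPrx1 down, therefore stays one open explanation beside it.

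In the second pattern, 10 probe sets differed between the lines at 0 h and 5586 at 48 h. Poorer precision at 0 h is argued against by the 5586 probe sets themselves, whose median 0 h difference in the 48 h direction was 2.64% of that at 48 h. A wrong line label on single or exchanged arrays at 0 h is argued against by the count at 0 h, which reached at most 18 with arrays exchanged between the lines or 1 array left out. All 3 resistant arrays at 0 h correlated slightly better with the susceptible arrays (0.9418, 0.9394 and 0.9394) than with their own group (0.9382, 0.9374 and 0.937). A wrong line label on a whole group at 0 h is nonetheless argued against by 7 of the 10 probe sets, which were called in the same direction at 48 h, on other arrays, with 0 in the opposite direction and 0.604 expected of independent lists. A single common response that is larger in the susceptible line covers 38.9% of the 2337 probe sets by their calls. These were called in the same direction in both lines and changed more in the susceptible. Another 722 were called in the susceptible line alone, where a weaker resistant change in the same direction may have missed its call. The share may therefore be higher, and a common response may describe part of the difference. It does not describe LOC543363, which moved in opposite directions at 48 h. Nor does it describe LOC543233, which rose in the resistant line. The LOC543233 fall in the susceptible line lost its call without susceptible 0 h replicate 1 and on the hybridisation control scale. Different responses of the genotypes stay open as the biological explanation, and what causes them was not tested. The line by infestation difference measures them together with any line difference in plant age or time of sampling, which cannot be told apart here.

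The third pattern is the low TaGlu1a signal in infested susceptible plants. A sequence difference under the probes would lower the signal at 0 h too. The 0 h difference was 0.82, without a call, with unadjusted 95% limits of 0.23 and 1.41. The upper limit lay under the bound of 2.04 set from the 48 h difference, which speaks only against a sequence difference that large. A smaller contribution of a sequence difference stays open, since both limits were positive. One deviating array is argued against by a line by infestation difference of at least 2.90 with any array left out. A lower TaGlu1a transcript level in susceptible plants under attack may be the cause, as a hypothesis found and tested on the same data. Signal from related TaGlu1 copies was not tested.

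Other splits of the arrays were counted for each comparison. For comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. Against 0 h the real split gave 14872 and 15595 calls in the resistant and 15458 and 17064 in the susceptible line, the highest other split 0, 1, 1 and 0, and 1 split, the real one, gave as many. From 24 h to 48 h the real splits gave 2390 (resistant) and 4687 (susceptible), the highest others 1 and 0. Between the lines 2 splits gave as many as the real 10 at 0 h, the highest other 12. At 24 h and 48 h the real splits gave 2382 and 5586, the highest others 125 and 0. For line by infestation, 10 of 100 splits gave at least 738 calls at 24 h (highest other 1124) and 9 of 100 gave at least 2337 at 48 h (highest other 2886), so chance is not excluded by these counts. All of the 10 and of the 9, the real split included, kept the infested arrays split by line. Those other than the real split exchanged arrays at 0 h, where few probe sets were called between the lines. With infested arrays of the lines mixed, the highest counts were 6 and 0.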

How the results depend on the processing

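Scaling on the hybridisation controls, and the overlaps and gene lists under other scalings, were chosen only after the result was seen. Over 310 values of 54 genes and 6074 alternatives, 5594 kept direction and side of the threshold, 449 kept the direction but lost the call, 11 gained a call and 20 reversed. PR5, XIP-I, WZF1, COMT1, TaPrx1, RPL9 and GAPN kept their calls against 0 h in both lines in every alternative.

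Counts against 0 h stayed within 1.5 times in every alternative, from 12805 to 13538 and from 13818 to 14412 in the resistant line at 24 h and 48 h, and from 13363 to 14799 and from 15163 to 15817 in the susceptible line, with 1 array left out. Such fits, which have fewer arrays, gave 1265 to 1667 (resistant) and 2904 to 4464 (susceptible) from 24 h to 48 h, 6 to 18, 1431 to 3231 and 3370 to 5764 between the lines at 0 h, 24 h and 48 h, and 476 to 1304 and 1266 to 2892 for line by infestation.

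Without the variance trend, counts were 1009 for the resistant line from 24 h to 48 h, 1544 between the lines at 24 h, and 390 and 1238 for line by infestation. Without moderation they were 6 between the lines at 0 h, and 414 and 1482 for line by infestation. Fits to the compared arrays only, with fewer arrays, gave 3 between the lines at 0 h and 1519 at 24 h. Array weights gave 3641 at 24 h. Scaling on the hybridisation controls gave 1405 for the resistant line from 24 h to 48 h, 3 between the lines at 0 h and 1487 for line by infestation at 48 h. For these counts the cause was not tested.

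That scaling also moved the split of directions. It gave 14041 higher and 3167 lower in the resistant line at 48 h, and 12824 and 3631 at 24 h and 17429 and 3559 at 48 h in the susceptible line. Between the lines it gave 1223 higher and 574 lower at 24 h, and for line by infestation 356 and 183 at 24 h and 351 and 1136 at 48 h. Median centring gave 9954 and 6101 in the susceptible line at 24 h, and 832 and 1674 between the lines at 24 h.

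Of 28 gene list calls, 0 held with an estimated correlation and 13 with 1 probe set per gene, which leaves fewer probe sets. The lists were also tested with fry, which does not set a list against the other probe sets. Its results are not given here. Asking for a 2-fold change as well, a stricter threshold, left overlaps of 4872 and 6028 between the lines at 24 h and 48 h, and of 5532 (resistant) and 6498 (susceptible) between the times.

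Reversals under hybridisation control scaling were FKBP70 (0.35, susceptible 48 h), TaGlu1a (0.42, resistant 48 h), PsbO (0.0408), tubb1 (0.28), Tubb4 (0.10) and H2A-3 (0.0085), each in the resistant line at 24 h, GSTZ1 (0.35 and 0.20 in the resistant line, 0.19 in the susceptible line at 24 h), AGP-S (0.38 and 0.0846, resistant), UBC1 (0.29 and 0.0541 for its probe sets, resistant 48 h) and TEF1 (0.0212, susceptible 24 h to 48 h). Of these only AGP-S at 24 h was called in the new direction (adjusted p = 0.0447), and the cause was not tested. Quantile normalization reversed PsbO (0.044, resistant 24 h) and UBC1 (0.0763, resistant 48 h), and the cause was not tested. With 1 array left out, the uncalled values in the resistant line at 48 h ran from -0.47 to 0.27 for TaGlu1a, 0.08 among them, and from -0.27 to 0.42 for WSZ2a, -0.06 among them.

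Taking the replicate number as a block gave 14804, 15586 and 2482 calls in the resistant line, 15466, 17044 and 4825 in the susceptible line, 10, 2475 and 5759 between the lines, and 842 and 2541 for line by infestation. Same-numbered arrays did not deviate together: their 45 correlations ran from -0.0397 to 0.0615, and 9 of 18 arrays correlated best with their own number. Signal over background limits dim probe sets, which the offset of 16 pulls toward no change.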

Other observations

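The groups of genes in this part were chosen only after the result was seen, as were the wheat control probe sets.

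G-6-PDH, of the oxidative pentose phosphate pathway, is carried on the array as a wheat control, and its 3 prime probe set had a signal of 1251 ± 9.31 (SD, n = 3) at 0 h and 1863 ± 313.9 at 48 h in the resistant line. In the susceptible line it went from 1229 ± 107 to 5796 ± 503.9, and the line by infestation difference was -1.67 (limma adjusted p = 4.63e-05). The 3 prime probe set of the sucrose synthase control went from 6577 to 7817 in the resistant and from 7710 to 12150 in the susceptible line, while its 5 prime probe set had no call in the resistant line. The 3 prime probe set of the ubiquitin control went from 28680 to 15830 and from 26480 to 14180. The 18S ribosomal RNA control had a signal of 391.5 in the resistant and 319 in the susceptible line at 0 h, and 136.5 and 83.3 at 48 h.

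Chloroplast genes as a group (30 probe sets of 8 genes) had 15 and 17 probe sets lower in the resistant line and 19 and 18 in the susceptible line. Redox and detoxification genes (12 probe sets of 5 genes, CAT1 and lgul among them) had 11, 10, 10 and 9 lower. Both groups hold genes already seen to fall, so their counts are not a test of the group.

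The size of the response was compared over probe sets called for the mean response of both lines. At 48 h the mean log2 change of 20906 such probe sets, in the direction of that mean response, was 1.045 ± 0.057 (SD, n = 3 arrays) in the resistant and 1.243 ± 0.022 in the susceptible line, and 60.8% of the probe sets changed more in the susceptible line. At 24 h the means over 19804 probe sets were 0.994 ± 0.045 and 1.087 ± 0.105. The SD covers the infested arrays only, since each line has one 0 h mean, and the difference in size was not tested.

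Probe sets with a line by infestation difference at 48 h fell into several kinds. Of the 2337, 909 were called in the same direction in both lines and changed more in the susceptible. Another 137 so called changed more in the resistant, and 160 were called in opposite directions. In the susceptible line alone 722 were called, 417 of them higher, and in the resistant line alone 406 were called, 249 of them higher. Among probe sets without a gene, the largest such differences at 48 h were 6.25 and -6.15.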
